A study of Homo sapiens with 6 samples.

How the data were processed

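RNA sequencing was done on total RNA from 6 samples of CAL-27 cells, 3 exposed to DHA and 3 to DMSO for 48 h. Total RNA was isolated with TRIzol, its integrity was screened on a Bioanalyzer, and libraries were built with the VAHTS Universal V10 kit, per the labels' protocols. The tools fastp, HISAT2, HTSeq and R (version 3.2.0) and the build GRCh38 are named in the submitters' processing notes. Their settings, their order, the annotation release and whether counting used the strand are not given in the sources used here. Fastp usually trims reads, HISAT2 is a spliced aligner and HTSeq a read counter that by default leaves out reads matching more than 1 gene or place. Such counting could lower or split the counts of near-identical or overlapping genes, so the values of paralogs, of genes with processed pseudogenes and of overlapping genes are uncertain, also where this is not said beside them.

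The deposited table holds whole-number read counts per gene, not normalized, in 1 column per library. It has 22503 gene rows, 15940 marked protein coding and 6563 non-coding. Each row held a count in at least 1 library, and none held a total or a class of unassigned reads. Columns were matched to libraries through the names in the labels, and no per-sample column was left unused. Gene identifiers of 21738 rows were found in the RefSeq table of GRCh38.p14, which gave the coordinates printed here (1-based). The library totals over genes ran from 35980670 to 38120267 counts.

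Groups were taken from the treatment labels. Genes were kept by edgeR's filterByExpr with its default minimum count of 10, which left 14649. Library sizes were scaled by TMM, and values are given as CPM, each library's counts relative to its scaled total, as mean ± SD of 3 libraries. Each gene was tested with edgeR's quasi-likelihood F test, two-sided, on the counts of the 6 libraries with treatment as the factor. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Log2 fold changes are DHA over DMSO, and their standard error (SE) was the fold change divided by the square root of F. A count of genes changed at least 2-fold applied an absolute log2 fold change of 1 on top of that threshold. The common biological coefficient of variation was 18.5%.

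Before the data were examined, 34 gene lists, 3 lists of markers of other cell types, the tests, the alternatives and the rule for named genes were fixed. The lists held 832 entries with the cell type markers, of which 814 were in the table. Each list was tested against all other genes with camera from limma on log2 CPM with a prior count of 2 and the preset correlation of 0.01, and adjusted over the 34 lists. Camera with the correlation estimated from the 6 libraries is given beside each list that passed. This variant also rests on the few residual degrees of freedom of the 6 libraries. It can thus give a larger p where members are not correlated. For pro-apoptotic genes the estimated correlation was -0.0130, below the preset one, yet the unadjusted camera p went from 0.0133 to 0.0553. A count adjusted over the list alone applies Benjamini-Hochberg to the members of that list. The rule for named genes took the 6 largest rises and the 6 largest falls among genes past the threshold with a mean of at least 5 CPM and no overlap between the groups. It also took up to 2 members of each list, those past the threshold with the largest fold change and a mean of at least 1 CPM, and 13 preset genes. This gave 53 genes, of which 43 passed the threshold, 28 higher and 15 lower. A further 41 genes were named after their values were seen and are marked so where they appear. A few members of the lists are not reported here by name.

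The alternatives were DESeq2 size factors, upper-quartile scaling and unscaled library totals, no filter, a minimum mean of 5 CPM, a replicate block, the DESeq2 Wald test, limma-voom, glmTreat against a 1.5-fold change, fry, and each library left out in turn. Fry tests the members of a list against no change, while camera tests them against all other genes. A correction for GC content and transcript length was added after the data were seen. It fitted the log2 CPM of each library against both by natural splines with 5 degrees of freedom and entered the trend as an offset. GENCODE 29 gene models gave these properties for 93.7% of the genes tested and for all members of the 34 lists. Tests of Gene Ontology, KEGG and Reactome terms, as annotated in the deposited table, were also added after the data were seen. They used a one-sided Fisher's exact test on terms of 10 to 500 genes, against the tested genes that carry any term of the same source.

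The edgeR fit was tested on simulated data with the means and library sizes of the real comparison of DHA with DMSO, over 14632 genes of which 200 were changed. It recovered 14.0% of 50 genes changed 1.5-fold, 60.0% of those changed 2-fold, 90.0% of those changed 4-fold and 100% of those changed 8-fold. Of its 137 calls, 5 were false. In this simulation changes of 1.5-fold were thus mostly missed with 3 libraries per group. The simulated genes varied independently of each other, without the GC trends and correlated lists of the real libraries. The shares recovered and falsely called may therefore differ in the real comparison. The software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.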

Results

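Transcript levels were measured in CAL-27 cells, an established line from a squamous cell carcinoma of the tongue with keratinocyte character, after 48 h with DHA or with the solvent DMSO. DHA was read as dihydroartemisinin, the active form of the artemisinin antimalarials, because the series is about artemisinin derivatives. Its dose is not given in the sources used here. There were 3 DMSO and 3 DHA libraries, with 35980670 to 37403613 counts over genes in the DMSO libraries and 35983061 to 38120267 in the DHA libraries. At this depth 3 counts corresponded to 0.0787 to 0.0834 CPM, and 18861 to 19269 genes had at least 1 count in a library. The labels do not say that the libraries came from separate cultures, so p-values measure the spread between these samples, which may be technical.

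The first principal component, with 47.5% of the variance, placed the 3 DMSO libraries apart from the 3 DHA libraries. Within groups, DMSO 1 lay far from the other DMSO libraries, and DHA 2 and DHA 3 lay at opposite ends of the second component, which held 20.2%. DMSO 2 and DMSO 3 were the closest pair. They still differed by more than sampling noise, with a mean chi-square of 7.05 per gene where counting error alone gives about 1, against 45.3 for the next closest pair, DHA 1 and DHA 2. All 6 were kept as separate samples.

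**Figure D1:**
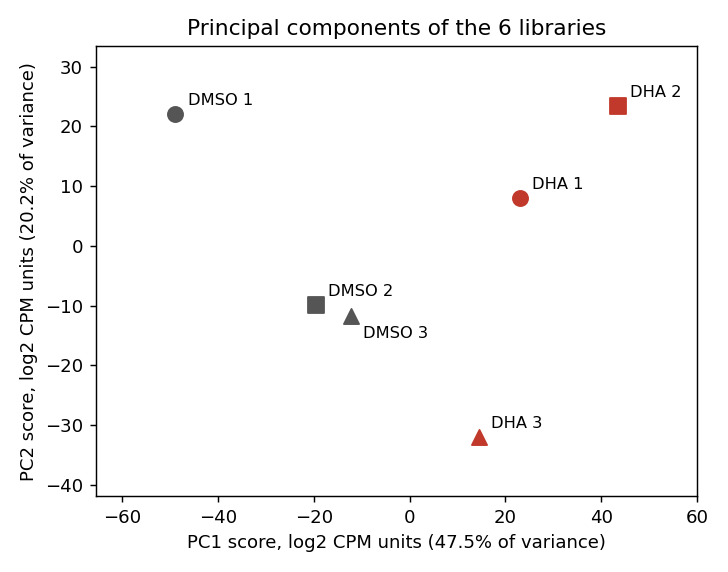
Scores of the 6 libraries on the first and second principal components of log2 CPM, with 47.5% and 20.2% of the variance on the x and y axes. Grey marks are DMSO and red marks DHA, and the shape gives the replicate number. DMSO 1 lies at -48.9 on the first component, and the DHA libraries lie at 14.4 to 43.5.

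The comparison of DHA with DMSO addresses which transcripts of a tongue carcinoma line differ after exposure to an artemisinin derivative. In DHA, 16 of 34 tested genes of the integrated stress response rose and 0 fell. Of the NRF2 targets 6 of 27 rose, of the chaperones and sensors of the endoplasmic reticulum 5 of 22, and of the ERK output genes 5 of 15, while 6 of 25 genes of the cholesterol synthesis list fell. As lists, these 4 did not pass with an estimated correlation (adjusted p = 0.287, 0.279, 0.287 and 0.257), and the integrated stress response did (adjusted p = 0.0217). Among single genes, the sterol exporters ABCA1 and ABCG1 fell and the EGFR ligand HBEGF rose. Cell cycle genes gave no call in edgeR. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 395 of 14649 genes changed, 161 higher and 234 lower, and 203 of them changed at least 2-fold, 69 higher and 134 lower. In all 395 the groups did not overlap, which held for 27.8% of all genes tested and is given by chance for 10%. The count varied strongly with the library left out. It was 178 without DMSO 1, 46 without DMSO 2, 168 without DMSO 3, 16 without DHA 1, 189 without DHA 2 and 789 without DHA 3. In each of these fits 0 of the 395 genes changed sign. This was nearly fixed beforehand, since groups that do not overlap keep their order when a library is left out. It therefore does not show how stable the directions are. The counts mark lost or gained calls. The count of genes changed at least 2-fold was 101, 46, 136, 16, 114 and 279 in the same order.

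The largest rises among well expressed genes belonged to AKR1C1, AKR1C2, CXCL2, UPP1, GDF15 and DDIT3. AKR1C1, an aldo-keto reductase, rose from 20.1 ± 5.77 to 115 ± 24.6 CPM (SD, n = 3), a log2 fold change of 2.52 ± 0.23 (SE, adjusted p = 0.00284 by edgeR). Its neighbor AKR1C2 rose from 20.8 ± 3.54 to 88.5 ± 21.4 CPM. These paralogs are nearly identical, so the division of reads between them is uncertain. They lie on chromosome 10 at 4963415 to 4983283 and 4987775 to 5018000 (GRCh38.p14). UPP1, which encodes uridine phosphorylase, rose from 232 ± 5.06 to 839 ± 90.6 CPM, a log2 fold change of 1.85 ± 0.13 (adjusted p = 0.00124 by edgeR). It lies on chromosome 7 at 48088704 to 48108736. The neutrophil chemokine CXCL2 rose from 6.08 ± 3.51 to 24.9 ± 5.06 CPM (adjusted p = 0.0378 by edgeR).

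The largest falls under the naming rule, with a mean of at least 5 CPM and no overlap between the groups, belonged to ABCA1, EDN2, CP, TGFB2, ABCG1 and ZNF488. ABCA1, the transporter that exports cholesterol to apolipoproteins, fell from 11.9 ± 4.63 to 2.02 ± 0.655 CPM, a log2 fold change of -2.56 ± 0.33 (adjusted p = 0.00959 by edgeR). It lies on chromosome 9 at 104781006 to 104928155. ABCG1, a sterol exporter to high-density lipoprotein on chromosome 21 at 42199689 to 42297244, fell from 12.8 ± 4.996 to 3.29 ± 0.707 CPM (log2 fold change -1.96 ± 0.30, adjusted p = 0.0159 by edgeR). TGFB2, a growth factor of the TGF-beta family, fell from 17.3 ± 2.93 to 3.65 ± 2.06 CPM. The endothelin gene EDN2 fell from 8.92 ± 5.18 to 1.68 ± 0.875 CPM, and CP, which encodes the ferroxidase ceruloplasmin, fell from 19.2 ± 13.9 to 3.76 ± 1.66 CPM. Both were highest in DMSO 1, with 14.9 CPM for EDN2 and 35.1 CPM for CP. Without DMSO 1 the log2 fold change went from -2.40 to -1.82 for EDN2 and from -2.35 to -1.57 for CP, and both calls were lost (adjusted p = 0.0759 each by edgeR). CP kept its call in 1 and EDN2 in 2 of the 6 fits that left out a library. ZNF488, a zinc finger gene, fell from 10.8 ± 2.81 to 2.99 ± 0.849 CPM.

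**Figure D2:**
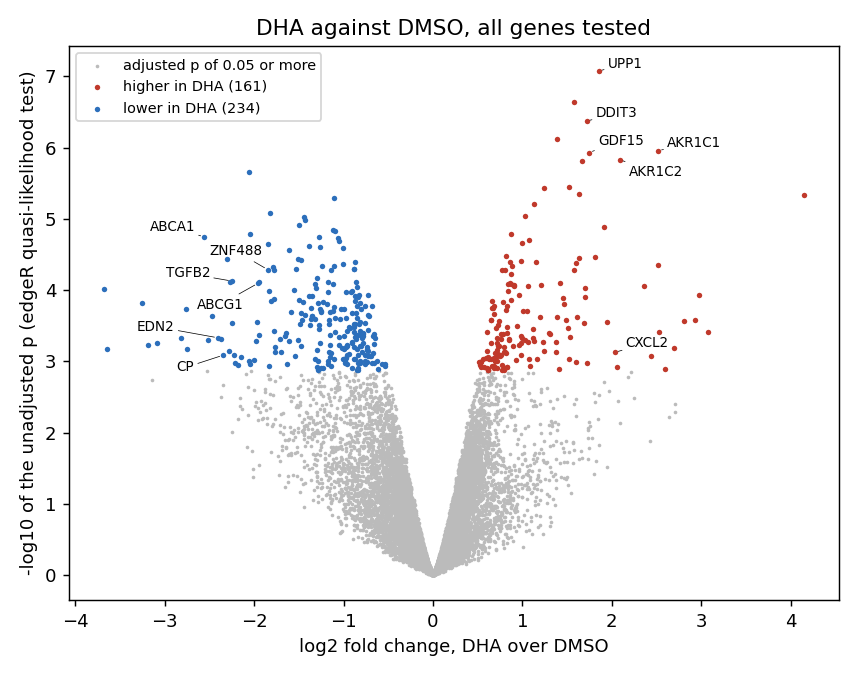
Log2 fold change of each of the 14649 genes, DHA over DMSO (x axis), against -log10 of the unadjusted p of edgeR's quasi-likelihood test (y axis). Red points are the 161 genes higher and blue points the 234 genes lower at an adjusted p under 0.05, grey points are the rest, and the names are the 6 largest rises and 6 largest falls under the naming rule.

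Of the 43 named genes that passed, 8 passed with any single library left out, namely AKR1C1, AKR1C2, UPP1, GDF15, DDIT3, SESN2, HBEGF and SQSTM1. CP, FTH1, ALAS1, BBC3, BIK, KRT6A, KRT6B, IFI44L, ARHGEF17 and ND4L each passed in only 1 of the 6 fits that left out a library. Without DHA 1, 35 of the 43 missed the threshold, without DMSO 2 it was 29, without DMSO 1 and without DMSO 3 it was 17 each, without DHA 2 it was 15 and without DHA 3 it was 2. Of the 40 calls among genes named after their values were seen, TRIB3 and PPP1R15A held in all 6 fits, SAA2 in none, and 9 in 1 fit, namely ATF4, CXCL3, COL4A1, COL4A2, LAMB1, GADD45A, SPRR2D, DUSP8 and LIF. Without DHA 1, 38 of the 40 missed the threshold, without DMSO 2 it was 35, without DMSO 3 it was 22, without DMSO 1 it was 18, without DHA 2 it was 14 and without DHA 3 it was 1. None of these genes changed sign in these fits, which the lack of overlap between their groups made nearly certain. In limma-voom, 6 calls of named genes were lost, those of CP, SCD, FTH1, EREG, ERN1 and SAA2. Above a mean of 5 CPM those of CXCL2, CP, SCD, FTH1, BBC3, KRT6A, EREG, ERN1, KLF4, GADD45A and DUSP8 were lost, and with unscaled library totals those of CXCL2, SCD, IFI44L, EREG, ERN1, SAA2, KLF4, COL4A1 and GADD45A.

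By camera with a preset correlation 15 of the 34 gene lists passed, and only the integrated stress response did with an estimated correlation. Of the 15, 8 missed the threshold in fry, namely the lists of immediate early genes, NF-kB and cytokines, interferon response, YAP targets, mitochondrially encoded genes, nuclear oxidative phosphorylation, ribosomal proteins and ribosome biogenesis. This list, made of targets of the translation-linked factors ATF4 and CHOP, gave the clearest group result. Of its 34 tested members 16 rose and 0 fell, and 22 rose when adjusted over the list alone. The median log2 fold change was 0.67, and the median deviation from the DMSO mean was 0.66, 0.59 and 0.66 in the 3 DHA libraries. The list passed camera with an adjusted p = 1.8e-15, and with an adjusted p = 0.0217 with an estimated correlation. DDIT3, which encodes CHOP, rose from 27.6 ± 1.101 to 90.8 ± 13.0 CPM (log2 fold change 1.72 ± 0.14, adjusted p = 0.00207 by edgeR). The stress cytokine gene GDF15 rose from 116 ± 13.3 to 388 ± 72.1 CPM. SESN2, a stress-induced inhibitor of mTORC1 that is also in the p53 list, rose from 30.3 ± 5.68 to 96.3 ± 5.82 CPM. CHAC1, a glutathione-degrading enzyme, rose from 13.4 ± 4.23 to 40.6 ± 2.03 CPM, with an adjusted p of 0.0573 without DHA 1. ATF3, also in the immediate early list, rose from 28.1 ± 2.72 to 56.3 ± 1.06 CPM. Named after their values were seen, TRIB3 rose by 1.58 on the log2 scale, PPP1R15A, a phosphatase subunit that restores translation, by 1.38, and ATF4 itself by 0.65. ATF4 kept its call only without DHA 3, and its adjusted p reached 0.174 without DHA 1.

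Chaperones and sensors of the endoplasmic reticulum rose in 5 of 22 tested members, in 8 when adjusted over the list alone, and fell in 0. The median log2 fold change was 0.26, with a camera adjusted p = 0.000312 and an adjusted p = 0.279 with an estimated correlation. DNAJB9 rose from 24.2 ± 4.11 to 48.4 ± 10.3 CPM and HERPUD1, a factor of protein degradation, from 46.5 ± 5.74 to 82.8 ± 7.25 CPM. The other 3 were named after their values were seen. The chaperone HSPA5 (BiP) rose by 0.65, XBP1 by 0.68 and the sensor ERN1 (IRE1) by 0.77 on the log2 scale. Heat shock genes of the cytosol gave 0 calls among 18 in edgeR, DESeq2 and limma-voom, with 3 at an unadjusted p under 0.05 and 0 when adjusted over the list alone (camera adjusted p = 0.324).

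NRF2 targets, which encode antioxidant and detoxifying enzymes, rose in 6 of 27 tested members, in 16 when adjusted over the list alone, and fell in 0. The median was 0.44, with a camera adjusted p = 1.4e-06 and an adjusted p = 0.287 with an estimated correlation. AKR1C1 and AKR1C2 led this list. Named after their values were seen, the sulfiredoxin gene SRXN1 rose by 0.87 and NQO1 by 0.87 on the log2 scale. HMOX1, the heme oxygenase gene and a common NRF2 target, was at 15.7 ± 9.17 CPM in DMSO and 13.2 ± 1.69 CPM in DHA (adjusted p = 0.692 by edgeR). DMSO 1 alone stood at 26.3 CPM, and without it the log2 fold change was 0.34 (adjusted p = 0.337 by edgeR). SQSTM1, which encodes the autophagy adaptor p62, rose from 692 ± 55.2 to 1643 ± 154 CPM (log2 fold change 1.25 ± 0.13, adjusted p = 0.00498 by edgeR).

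Autophagy and lysosome genes, SQSTM1 among them, went both ways, with 2 higher and 1 lower of 26, and 4 higher and 1 lower when adjusted over the list alone. MAP1LC3B, named after its values were seen, rose by 0.86 on the log2 scale, and the protease gene CTSB fell from 4463 ± 604 to 2422 ± 353 CPM. The list median was -0.03 while its mean was 0.06 and camera pointed up, without passing (adjusted p = 0.594).

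Ferroptosis suppressors held 1 rise and 1 fall among 18, and 5 rises and 2 falls when adjusted over the list alone, with a camera adjusted p = 0.0724, 0.0483 without DHA 1 and 0.0430 with no filter. FTH1, the ferritin heavy chain gene, rose from 4040 ± 106 to 6989 ± 1710 CPM at the edge of the threshold (adjusted p = 0.0496 by edgeR). It kept the call only without DHA 3, and its highest adjusted p with another library left out was 0.158. In limma-voom the list held no call, as FTH1 (adjusted p = 0.0507) and SCD (0.0537) missed the threshold. Reads of FTH1 and FTL can also match processed pseudogenes, so their counts are uncertain. FTL, named after its values were seen, was at 995 ± 12.6 CPM in DMSO and 1561 ± 377 CPM in DHA (adjusted p = 0.0834 by edgeR). It passed without DHA 3 (adjusted p = 0.0268), with no filter (0.0350), in DESeq2 (0.0138) and after a correction for GC content and length that was chosen after the results were seen (0.0416). SLC7A11, the cystine transporter, was at 115 ± 3.19 and 215 ± 83.7 CPM (log2 fold change 0.91 ± 0.23, adjusted p = 0.0736 by edgeR), and DHA 3 alone stood at 311 CPM. Its adjusted p was 0.0408 without DHA 3, 0.0367 without DHA 2, 0.0122 with no filter and 0.00482 after the correction, and it also passed in DESeq2. GPX4, a central suppressor of ferroptosis, was at 137 ± 2.74 and 136 ± 33.7 CPM (adjusted p = 0.986 by edgeR). Drivers and markers of ferroptosis gave 1 rise, CHAC1, among 16, also when adjusted over the list alone (camera adjusted p = 0.630). Their median was near 0 and slightly negative, while camera pointed up.

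Iron and heme genes rose in 2 of 29 tested members, in 3 when adjusted over the list alone, and fell in 0 (camera adjusted p = 0.136). They were FTH1 and ALAS1, the rate-limiting enzyme of heme synthesis, which rose from 33.4 ± 2.40 to 55.0 ± 6.37 CPM. The transferrin receptor gene TFRC was at 299 ± 144 CPM in DMSO and 523 ± 133 CPM in DHA (adjusted p = 0.238 by edgeR), with DMSO 1 lowest at 133 CPM. Metallothioneins, which bind zinc and copper, gave 0 calls among 6 in edgeR and limma-voom and 1 in DESeq2, with 1 at an unadjusted p under 0.05 and 1 rise when adjusted over the list alone. Their median was -0.02, while their mean and camera were positive (adjusted p = 0.515, and 0.0478 without DMSO 1).

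Genes of the cholesterol synthesis list fell in 6 of 25 tested members and rose in 0. Adjusted over the list alone, 12 fell and 1 rose. The median log2 fold change was -0.40, and -0.31, -0.37 and -0.34 in the 3 DHA libraries against the DMSO mean. The camera adjusted p was 6.7e-05, and the list had an adjusted p = 0.257 with an estimated correlation. INSIG1, a sterol sensor partner, fell from 66.4 ± 13.5 to 30.7 ± 5.84 CPM, and STARD4, a sterol carrier gene, from 70.7 ± 16.4 to 33.1 ± 6.91 CPM. MSMO1, a sterol oxidase gene named after its values were seen, fell by 0.88 on the log2 scale. SCD, a fatty acid desaturase in the list of ferroptosis suppressors, fell from 1462 ± 684 to 625 ± 52.5 CPM (adjusted p = 0.0472 by edgeR). DMSO 1 alone stood at 2251 CPM for SCD, whose log2 fold change was -1.23, and -0.77 without DMSO 1. The call of SCD was lost without DMSO 2, DHA 1, DHA 2 or DHA 3, up to an adjusted p of 0.135.

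**Figure D3:**
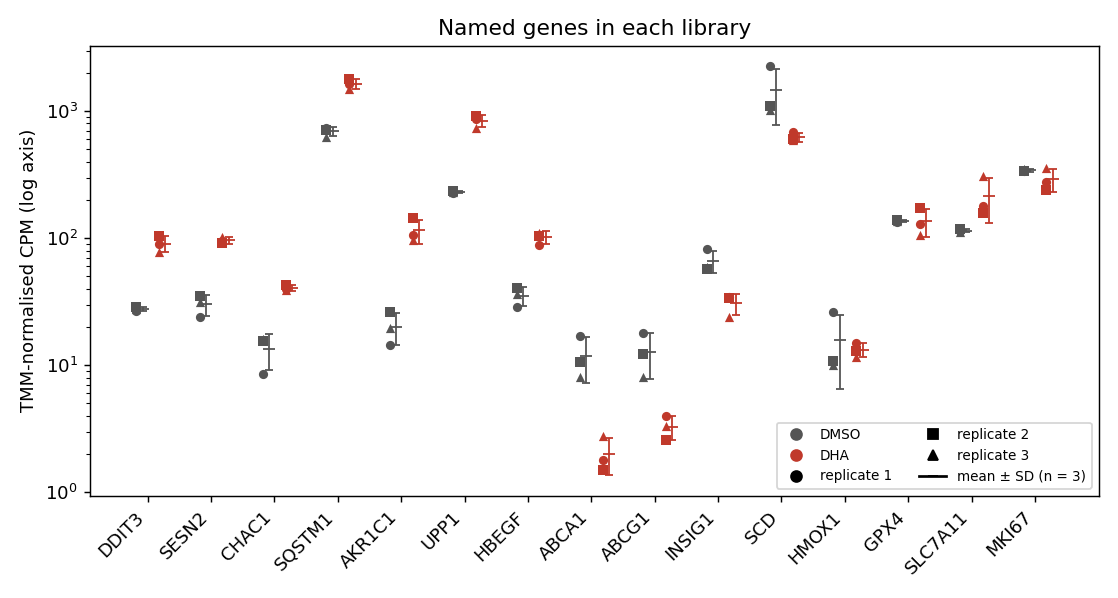
TMM-normalised CPM on a log axis for 15 named genes in each library, grey for DMSO and red for DHA, with the shape giving the replicate and the bar beside the points the mean ± SD of 3 libraries. DDIT3, SESN2, SQSTM1 and UPP1 lie higher in each DHA library than in any DMSO library and ABCA1 and ABCG1 lower, while the groups of HMOX1, GPX4 and MKI67 overlap.

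ERK output genes, the feedback and target genes of MAP kinase signaling, rose in 5 of 15 tested members, in 8 when adjusted over the list alone, and fell in 0. Their median was 0.47, with a camera adjusted p = 6.1e-05 and an adjusted p = 0.287 with an estimated correlation. FOSL1, an AP-1 subunit, rose from 108 ± 10.9 to 236 ± 12.2 CPM (adjusted p = 0.00598 by edgeR) and DUSP5, an ERK phosphatase, from 39.5 ± 5.44 to 78.0 ± 2.82 CPM. Named after their values were seen, ETV5 rose by 0.91, DUSP4 by 0.87 and PHLDA1 by 0.83 on the log2 scale. EGFR family genes and ligands held 3 rises among 10, with 3 higher and 2 lower when adjusted over the list alone, and a camera adjusted p = 0.250. The 3 were all ligands. HBEGF rose from 35.1 ± 5.85 to 101 ± 11.7 CPM (log2 fold change 1.53 ± 0.16, adjusted p = 0.00498 by edgeR), EREG from 19.9 ± 2.61 to 42.2 ± 15.3 CPM, and AREG, named after its values were seen, 2.01-fold.

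Immediate early genes rose in 3 of 18 tested members and fell in 0, with 4 higher and 1 lower when adjusted over the list alone. The median was 0.25, with a camera adjusted p = 0.0219 and an adjusted p = 0.571 with an estimated correlation. The list also missed the threshold without DMSO 3 (adjusted p = 0.348), without DHA 2 (0.0621), without DHA 3 (0.0652), with no filter (0.0582) and in fry. Besides ATF3, DUSP1 rose from 7.71 ± 1.07 to 13.9 ± 0.825 CPM, and KLF4, named after its values were seen, by 0.69 on the log2 scale.

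NF-kB targets and cytokines rose in 3 of 26 and fell in 1, with 9 higher and 2 lower when adjusted over the list alone. The median was 0.20, with a camera adjusted p = 0.00263 and an adjusted p = 0.571 with an estimated correlation. CSF3, the granulocyte growth factor gene, rose from 0.332 ± 0.124 to 2.56 ± 1.67 CPM at low counts, with DHA 2 at 4.48 CPM. Its log2 fold change was 2.93, and 2.25 without DHA 2, and it kept its call in 2 of the 6 fits that left out a library. CXCL2 also rose, and the pair named after their values were seen went apart, with log2 fold changes of 1.31 for CXCL3 and -0.61 for SAA2. CXCL2 and CXCL3 are close paralogs, as are SAA2 and SAA1, so their counts are uncertain. Interferon response genes fell in 2 of 26 and rose in 0, with the same 2 when adjusted over the list alone. Their median was -0.19, with a camera adjusted p = 0.00642 and an adjusted p = 0.571 with an estimated correlation, and 0.0744 in the preset test without DMSO 3. IFI44L fell from 14.2 ± 3.09 to 7.08 ± 1.27 CPM and IFIT1 from 24.2 ± 2.55 to 14.1 ± 1.11 CPM. IFIT1 missed the threshold after the GC and length correction (log2 fold change -0.58 against -0.78, adjusted p = 0.109 by edgeR). IFI44L kept its call in 1 and IFIT1 in 3 of the 6 fits that left out a library. The STAT3 pathway gave 0 calls among 18 in edgeR and limma-voom and 4 in DESeq2, with 6 at an unadjusted p under 0.05. Adjusted over the list alone, 1 was higher and 2 lower (camera adjusted p = 0.630). STAT3 itself was at 250 ± 43.7 and 211 ± 11.2 CPM (adjusted p = 0.351 by edgeR).

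Genes of keratinocyte differentiation rose in 3 of 21, also when adjusted over the list alone, and fell in 0. The median was 0.31, with a camera adjusted p = 0.00894 and an adjusted p = 0.350 with an estimated correlation. The preset test gave 0.962 where genes under a mean of 5 CPM were left out, since the 3 that rose were scarce. SPRR1A rose from 0.360 ± 0.130 to 2.08 ± 0.250 CPM and SPRR1B from 1.15 ± 0.591 to 5.94 ± 0.914 CPM, and SPRR2D, named after its values were seen, by 2.52 on the log2 scale. These cornified envelope genes are close paralogs, so their counts are uncertain. Basal keratinocyte genes held 2 rises among 20, while 2 were higher and 6 lower when adjusted over the list alone, and camera pointed down with an adjusted p = 0.0813, and 0.0328 without DMSO 3. The 2 rises, KRT6B from 6.26 ± 0.794 to 13.6 ± 3.34 CPM and KRT6A from 89.4 ± 15.3 to 150 ± 16.5 CPM, are close paralogs better known from activated keratinocytes, so their counts are uncertain.

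Mesenchymal and invasion genes split, with 2 higher and 4 lower of 28, and 3 higher and 6 lower when adjusted over the list alone (camera adjusted p = 0.0818, and 0.0472 downward after the GC and length correction). MMP1, a collagenase gene, rose from 4.39 ± 1.66 to 14.3 ± 2.27 CPM, and PLAU, named after its values were seen, rose by 1.08 on the log2 scale. TGFB2 fell, as did 3 genes named after their values were seen, THBS1 from 568 ± 187 to 201 ± 36.8 CPM, SPARC by 0.88 and PDPN by 0.72 on the log2 scale. The mesenchymal marker VIM was at 0.440 ± 0.184 CPM in DMSO and 0.510 ± 0.311 CPM in DHA, and CDH1 (E-cadherin) at 445 ± 79.4 and 352 ± 34.6 CPM (adjusted p = 0.256 by edgeR). Among 18 epithelial junction genes only CLDN1 passed, and 5 fell when adjusted over the list alone (camera adjusted p = 0.133). CLDN1, a tight junction gene, fell from 1129 ± 101 to 611 ± 41.8 CPM (adjusted p = 0.0125 by edgeR). YAP targets fell in 2 of 17 and rose in 0, with 8 lower and 1 higher when adjusted over the list alone. Their median was -0.38, with a camera adjusted p = 0.00336 and an adjusted p = 0.571 with an estimated correlation. The 2 were TGFB2 and ARHGEF17, which fell from 49.1 ± 4.75 to 28.99 ± 2.32 CPM. Wnt targets gave 0 calls among 10 in edgeR and limma-voom and 1 in DESeq2, with 3 at an unadjusted p under 0.05 and 1 lower when adjusted over the list alone (camera adjusted p = 0.594).

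Pro-apoptotic genes rose in 2 of 18, also when adjusted over the list alone, and fell in 0. The median was 0.20, with a camera adjusted p = 0.0301 and an adjusted p = 0.313 with an estimated correlation. The preset test missed the threshold without DMSO 2 (0.0507) and without DMSO 3 (0.0649). BIK rose from 17.1 ± 1.42 to 33.2 ± 8.05 CPM and BBC3 (PUMA) from 15.5 ± 2.19 to 27.4 ± 4.22 CPM. Each kept its call in only 1 of the 6 fits that left out a library. Among 10 anti-apoptotic genes BCL2A1 rose from 0.988 ± 0.127 to 3.47 ± 0.273 CPM, and 2 rose when adjusted over the list alone (camera adjusted p = 0.239). P53 targets gave 3 rises and 1 fall among 27, with 5 higher and 3 lower when adjusted over the list alone. The camera adjusted p was 0.161. Fry, which tests against no change and not against the other genes, gave an adjusted p = 0.0143. The rises were SESN2, BBC3 and GADD45A, the last named after its values were seen with a log2 fold change of 0.72, and the fall was PLK2, named likewise at -0.67. CDKN1A, the p21 gene, was at 53.1 ± 23.6 and 85.5 ± 11.6 CPM (log2 fold change 0.69 ± 0.26, adjusted p = 0.190 by edgeR), with DMSO 1 at 80.3 CPM. Without DMSO 1 the log2 fold change was 1.12 and passed (adjusted p = 0.0247 by edgeR), and it passed in none of the other 5 such fits.

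Cell cycle genes gave almost no call at this depth and spread. Among 32 genes of G1/S and DNA replication edgeR, DESeq2 and limma-voom gave 0 calls, with 2 at an unadjusted p under 0.05 and 0 when adjusted over the list alone (camera adjusted p = 0.250, and 0.0328 upward without DMSO 3). Among 34 genes of G2/M and mitosis edgeR and limma-voom gave 0 calls and DESeq2 gave 1, with 5 at an unadjusted p under 0.05 and 0 when adjusted over the list alone (camera adjusted p = 0.963). The proliferation marker MKI67 was at 342 ± 7.60 and 291 ± 59.9 CPM (log2 fold change -0.23 ± 0.16, adjusted p = 0.417 by edgeR), and CCND1 (cyclin D1) at 210 ± 49.6 and 226 ± 26.8 CPM (adjusted p = 0.774 by edgeR). Homologous recombination genes gave 0 calls among 24 in the 3 tools, with 1 at an unadjusted p under 0.05. Replication-dependent histones gave 0 among 8 in the 3 tools, with 0 at an unadjusted p under 0.05. Both gave 0 calls when adjusted over the list alone, with camera adjusted p of 0.877 and 0.597. Glycolysis and hypoxia genes gave 0 calls among 27 in the 3 tools and 0 when adjusted over the list alone, with 3 at an unadjusted p under 0.05. Their median was -0.32, with 6 of 27 fold changes positive and a camera adjusted p = 0.133. Camera passed without DMSO 2 (adjusted p = 0.0107), DMSO 3 (0.0127) or DHA 1 (0.0143), but not without DMSO 1 (0.401), DHA 2 (0.186) or DHA 3 (0.809). With an estimated correlation the adjusted p was 0.823.

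Growth and respiration lists shifted by small amounts without any single call. All 44 ribosomal protein genes had positive fold changes, with a median of 0.27, and edgeR, DESeq2 and limma-voom gave 0 calls, with 0 at an unadjusted p under 0.05. Camera gave an adjusted p = 0.000133, against an adjusted p = 0.729 with an estimated correlation and 0.231 in the preset test without DHA 2. Nuclear oxidative phosphorylation genes had a median of 0.25 over 36 members, also with 0 calls in the 3 tools and 0 at an unadjusted p under 0.05. The camera adjusted p was 0.00263, and the adjusted p was 0.729 with an estimated correlation, 0.263 in the preset test without DHA 2 and 0.0650 without DMSO 1. Ribosomal protein genes took 5.55 ± 0.0443% of counts in DMSO and 6.63 ± 1.46% in DHA, with 8.16% in DHA 2 and 5.25% in DHA 3. Ribosome biogenesis genes had a median of 0.28 over 24 members with 0 calls in the 3 tools and 2 at an unadjusted p under 0.05. Camera gave an adjusted p = 0.00642 and an adjusted p = 0.729 with an estimated correlation, and the preset test gave 0.545 without DMSO 1 and 0.0652 without DHA 3. None of these 3 lists gave a call when adjusted over the list alone.

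Mitochondrially encoded genes fell in 1 of 13 and in 2 when adjusted over the list alone. Their median was -0.23, with a camera adjusted p = 0.0219 and an adjusted p = 0.641 with an estimated correlation. The preset test gave 0.196 without DMSO 2, 0.0834 without DMSO 3 and 0.244 without DHA 3. ND4L fell from 1416 ± 156 to 820 ± 120 CPM and shares a transcript with the overlapping ND4, so its count is uncertain. Mitochondrial genes took 6.40 ± 1.07% of counts in DMSO and 5.15 ± 0.480% in DHA, where DMSO 1 at 5.24% lay within the DHA range of 4.63 to 5.58%.

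**Figure D4:**
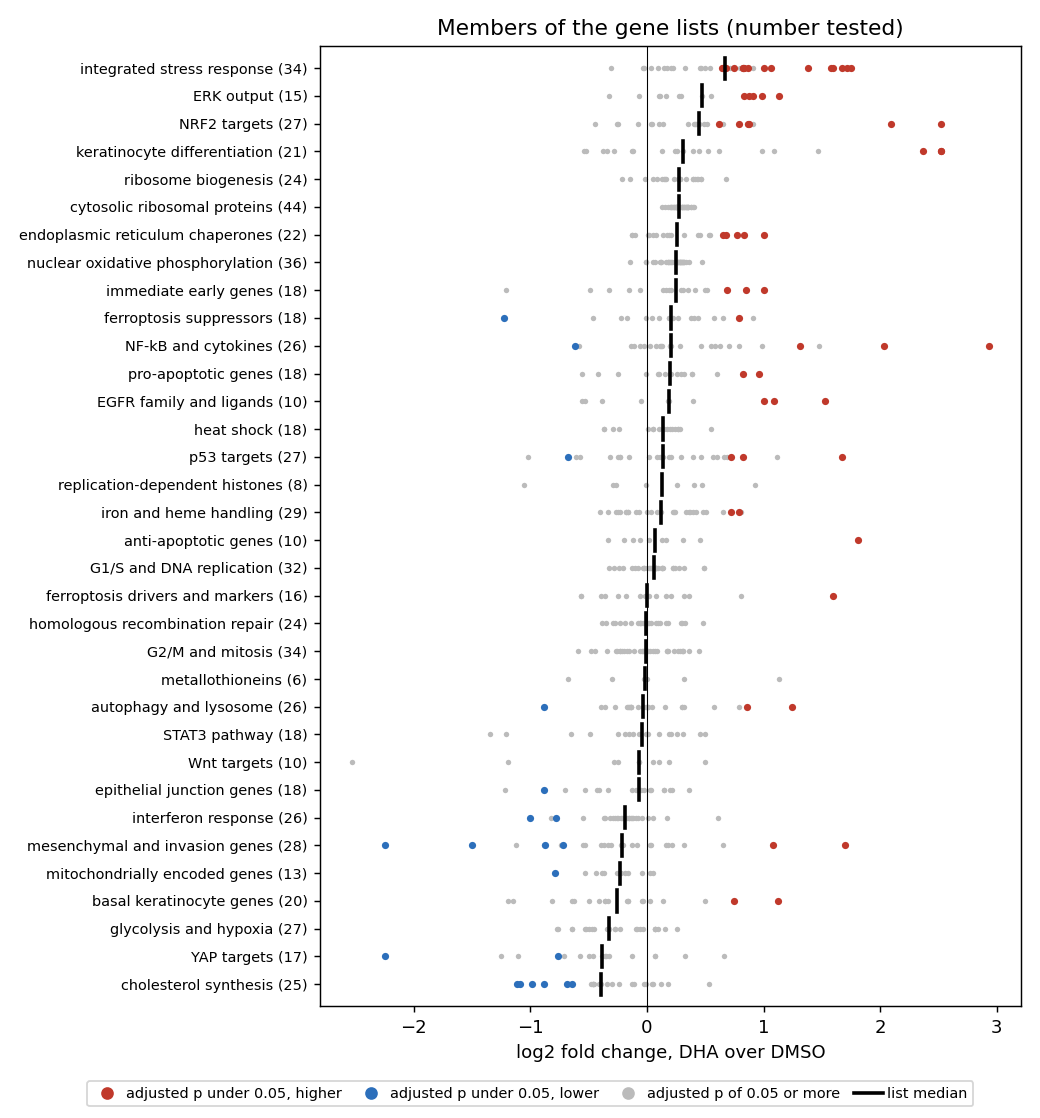
Log2 fold changes, DHA over DMSO (x axis), of the tested members of the 34 gene lists (y axis, with the number tested), sorted by the list median (black bar). Red and blue points are members higher and lower at an adjusted p under 0.05 and grey points the rest. The integrated stress response has the highest median, 0.67, and cholesterol synthesis the lowest, -0.40.

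Markers of other cell types were mostly scarce. Their highest levels are given as CPM of the unscaled library totals. Of 9 fibroblast markers that could be matched, 3 exceeded 1 CPM in a library, led by COL1A1 at 20.8 CPM. Of 7 endothelial markers 1 did, CDH5 at 26.1 CPM, and of 5 immune markers 3 did, led by CD68 at 42.4 CPM. CD14, named after its values were seen, was the only marker that passed and fell from 5.64 ± 0.912 to 2.20 ± 0.479 TMM-scaled CPM (log2 fold change -1.36, adjusted p = 0.0240 by edgeR).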

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

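The correction for GC content and transcript length was chosen only after the results were seen, and the other alternatives before. The 395 genes changed became 649 with no filter, 251 above a mean of 5 CPM, 1135 in the DESeq2 Wald test, 658 after the correction, and 16 to 789 with 1 library left out. The 203 genes changed at least 2-fold became 322, 96, 385, 253 and 16 to 279 in the same order, and 16 passed glmTreat against 1.5-fold. The replicate block gave 1272 and 426 genes, and 1766 and 438 with the correction. In the block SLC7A11, TFRC, CDKN1A, FTL and the glycolysis list also passed, and with both the pro-apoptotic list did not. Same-numbered libraries were not taken as pairs, since the sources do not pair them. Their deviations correlated at r = 0.26, 0.12 and -0.04 across genes. Libraries 1 and 2 of each group correlated best with their own number, and libraries 3 with number 2. Another scaling gave 346 to 395 genes, and 33.1% to 40.5% of them were higher against 40.8%. Of the 34 lists 15 passed camera, 1 did with an estimated correlation, the integrated stress response, and 8 passed fry. Apart from the correction the cause was not tested, except that fewer genes or libraries entered some fits.

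Over 94 named genes and 1497 alternative values, 278 lost a call, 18 gained one and 0 changed direction with a call. The same counts for the 34 lists were 39, 13 and 0 of 542. For called genes the lack of reversals was nearly fixed beforehand, since their groups did not overlap. At this depth 3 counts lie at 0.0834 CPM or less in each library, so changes of scarcer genes could not be seen. The filter also left some genes above that level untested, such as the endothelial marker TEK, which reached 0.508 CPM of unscaled library totals.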

Other observations

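The tests of annotation terms, and the tests of GC content and length, were chosen only after the results were seen. Among genes higher in DHA, the Reactome term for the response of EIF2AK1 (HRI), the kinase that senses heme deficiency, held 8 of its 15 tested genes where 0.216 were expected by chance. They were ATF3, ATF4, ATF5, CEBPG, CHAC1, DDIT3, PPP1R15A and TRIB3 (adjusted p = 1.2e-08, one-sided Fisher's exact test). All 8 are in the fixed list of the integrated stress response, so the term restates that result and does not single out HRI or heme. The Reactome term for the unfolded protein response held 12 of 86 genes (adjusted p = 1.9e-06, same test). The PERK term held 8 of 32 (adjusted p = 5.3e-06). Both held ATF3, ATF4, CEBPG and DDIT3 of the fixed integrated stress response list. Both also held HERPUD1 and HSPA5 of the fixed list of endoplasmic reticulum chaperones and sensors, and the first also its DNAJB9, ERN1 and XBP1. These 2 terms thus largely restate the results of those lists. Genes of these terms outside the naming rule were named after their values were seen. MAP kinase phosphatases rose in 4 of 10 (DUSP1, DUSP4, DUSP5 and DUSP8, adjusted p = 0.00233). Of the 6 fits that left out a library, DUSP8 kept its call in 1, DUSP1 in 2, and DUSP4 and DUSP5 in 4. Growth factor genes rose in 8 of 81, among them LIF and INHBE besides the EGFR ligands (adjusted p = 0.00247). Here LIF kept its call in 1 such fit, INHBE, EREG and CSF3 in 2, AREG in 4, and HBEGF and GDF15 in all 6. Keratinization genes rose in 5 of 25 (adjusted p = 0.00293), but these are KRT6A, KRT6B, SPRR1A, SPRR1B and SPRR2D, paralogs that can share reads and that Fisher's test takes as independent. KRT6A, KRT6B and SPRR2D each kept the call in 1 of the 6 fits that left out a library, and the fixed list of keratinocyte differentiation had an adjusted p = 0.350 with an estimated correlation and 0.962 in the preset test above a mean of 5 CPM.

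Among genes lower in DHA, collagen-containing extracellular matrix held 19 of 202 tested genes where 3.37 were expected (adjusted p = 3.5e-06, one-sided Fisher's exact test). They included basement membrane genes named after their values were seen. On the log2 scale, COL4A1 fell by 0.74, COL4A2 by 0.53, LAMA5 by 0.74 and LAMB1 by 0.66. LAMA5 kept its call in 2 and the other 3 in 1 of the 6 fits that left out a library. After the GC and length correction LAMA5 missed the threshold (adjusted p = 0.0555 by edgeR), though its log2 fold change was -0.70 against -0.74. Cholesterol homeostasis held 9 of 50 genes (adjusted p = 0.000125). Binding of fibroblast growth factors held 5 of 16, with the receptors FGFR2, FGFR3 and FGFR4 among them (adjusted p = 0.00248). In all, 20 Gene Ontology terms of 3228 passed for higher and 16 for lower genes, 4 and 5 KEGG terms of 323, and 6 and 10 Reactome terms of 1398.

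The 6 libraries can be split into 3 and 3 in 10 ways, too few to bring a share under 0.05. The real split gave 395 genes and 203 changed at least 2-fold, and the highest of the others gave 0 of each, with up to 1213 at an unadjusted p under 0.05. For both counts 1 of the 10 splits, the real one, reached the real value. For lists passing camera, 2 of the 10 splits reached the real value of 15, since DMSO 1, DMSO 2 and DHA 1 against the rest also gave 15, so this count does not set the real split apart. With an estimated correlation no other split gave a list. Each other split holds DHA and DMSO libraries in both groups, so a treatment difference would widen its spread within groups and lower its counts. The other splits thus do not show what samples without a treatment difference would give.

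ABCA1 and ABCG1, which are raised by the liver X receptors when sterols are high, fell, as did 6 of 25 genes of the cholesterol synthesis list, which the SREBP factors raise when sterols are low (list adjusted p = 0.257 with an estimated correlation). Neither a GC and length correction nor DMSO 1 accounts for the whole, as the median over these 27 genes kept a share of 0.956 after the correction and 0.898 without DMSO 1. A hypothesis stated before the test was lower activity of the liver X receptors on 11 other tested targets, and their camera p was 3.1e-05 (0.0120 with an estimated correlation, and at least 0.0157 in the other splits with the preset one). Of the 11, 10 had negative fold changes and 4 fell, MYLIP (log2 fold change -1.14), SREBF1 (-1.10) and FASN (-0.66), named after their values were seen, and SCD (-1.23), of which SCD (-0.96, adjusted p = 0.0547) and FASN (-0.62, adjusted p = 0.0655) missed the threshold after the correction and each passed in 2 of 6 leave-one-out fits. This fits the hypothesis, but SCD and FASN also follow SREBP1, 2 of the 11 belong to other lists fixed here, and receptor activity was not measured, so a joint loss of lipid gene transcription may serve as well.

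Ribosomal protein and oxidative phosphorylation genes had a median log2 fold change of 0.27 over 80 genes, which fell to 0.06 without DHA 2, a share of 0.231. Against the DMSO mean, the median of ribosomal protein genes was 0.22 in DHA 1, 0.62 in DHA 2 and -0.11 in DHA 3. That of oxidative phosphorylation genes was 0.17, 0.56 and -0.04. The pattern may therefore rest mainly on DHA 2, but DHA 3 did not share it and also lowered the median without DHA 2. Deviations from the group mean correlated with GC content across genes at r = 0.43 in DHA 2 and -0.48 in DHA 3. The GC and length correction left a share of 0.826, which argues against those trends as the whole cause. What set DHA 2 and DHA 3 apart was not tested.

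The same correction raised the count of changed genes from 395 to 658. Over 20 corrections with GC content and length shuffled among genes the highest count was 414, which is consistent with library-specific trends that widen the spread within groups. No biological explanation was tested for this pattern.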
